A study of Mus musculus with 12 samples.

How the data were processed

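RNA (200 ng) of mouse bone marrow-derived macrophages was hybridised to single-colour Agilent arrays, 12 in all, with 3 arrays in each of the untreated, acute, tolerant and recovered groups. Per the labels, cells came from female C57BL/6 mice aged 6 to 8 weeks, were differentiated for 7 days in L929-conditioned medium, and the 3 replicates of a group were independent experiments. Whether each used separate animals is not stated. P-values of the main model measure the spread between the 3 arrays within a group, pooled over the 4 groups and without pairing by experiment.

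Per the file headers, the scanner files hold spot intensity values that Agilent Feature Extraction 10.7.3.1 background subtracted and detrended within each array, not normalized between arrays, with probe positions on mm9. The authors' matrix holds log2 values with the same quartiles, median (5.34) and highest value in every column but different lowest values (2.58 on untreated array 3), which by the look of the values may have been quantile normalized between arrays, with ties at the low end, and were not centred; the submitters' notes name limma without a version, and background correction is not stated. Each matrix column matched its own array best (12 of 12, r of at least 0.973 across spots). The matrix was used as an alternative only.

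The processed intensity was put on a log2 scale, the 75th percentile of each array (8.04 to 9.38) was subtracted and the mean of the 12 percentiles was added back. Of 62976 spots 59305 were not controls, and they carried 55681 probes. Spots that the scanner software called outliers (135 to 233 per array) were left out, which removed 118 probes, and 0 spots were saturated. Probes were kept if well above background on all 3 arrays of at least 1 group (28056), and the brightest probe stood for a gene. This gave 20469 genes, of which 5345 had several probes, 14265 were matched to the reference gene names (GRCm38.p6, names only), 2752 were lincRNA loci and 3452 were other names. Probes were matched by accession (26419), symbol (3993) or synonym (826), and 24443 were not matched. Genes with probes called in opposite directions numbered 34, 25 and 76 in acute, tolerant and recovered against untreated cells, 11 in tolerant against acute, 12 in recovered against tolerant and 0 in recovered against acute cells (limma). Exons and untranslated regions at the probes were not analysed here. Control spots were left out.

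All 12 arrays were fitted in 1 linear model with limma 3.58.1 (lmFit, eBayes) in R 4.3.3 (tables were read with version 1.17.8 of data.table), with 8 residual and 3.06 prior degrees of freedom and a median within-group standard deviation of 0.285. The 6 comparisons used two-sided moderated tests with Benjamini-Hochberg adjustment over genes, and a gene was called at an adjusted p under 0.05. An F-test over the 4 groups called 8212 genes. The 20 gene lists, fixed before the data were examined, were tested with camera (preset correlation 0.01), adjusted over the 20 lists. With an estimated correlation, the calls that held were those of cytokines, chemokines, interferon response and antimicrobial effectors in each group against untreated cells. With the replicate block as well, 9 calls held, those of chemokines and interferon response in each group, of cytokines in tolerant cells, and of interferon response in tolerant against acute and recovered against tolerant cells. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

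Named genes followed a rule fixed before the data were examined. It took a panel of 16 genes, and per comparison the 8 largest rises and 8 largest falls among called genes without overlap and above background on all 3 arrays of the higher group. It added up to 4 called members per list, or the member with the smallest p, up to 8 genes higher and 8 lower in recovered than both other LPS groups, and up to 8 tolerised and 8 induced genes with the largest changes.

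The arrays lay on 3 slides scanned on 2 days: replicate 1 of untreated, acute and tolerant cells on the first slide, replicate 2 of all groups and recovered replicate 1 on the second, and replicate 3 of all groups on the third, which was scanned on the second day. After removal of group means, the 18 pairs of arrays with the same replicate number correlated across genes at r from 0.275 to 0.773 (median 0.449), and the 36 pairs with different numbers had a median of -0.368. Among the latter, pairs of replicates 1 and 2 had r from 0.06 to 0.337. Pairs of replicate 3, scanned on the second day, with replicate 1 or 2 had r from -0.653 to -0.296. Since group means of 3 arrays were removed, positive r within a number brings negative r between numbers. The negative median is therefore no separate evidence. The 3 pairs with the same number on different slides had r from 0.312 to 0.375, and the 3 pairs on the same slide with different numbers from 0.116 to 0.337. Genes are not independent replicates. The replicate number and the slide were therefore each tried as a block.

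Other alternatives were normexp background (offset 50), quantile normalization, no filter on dim probes, the mean of a gene's probes, an intensity trend in the variance prior, only the groups of a comparison, the authors' values, a 2-fold threshold and leaving out each array. Leaving out the second scan day, and the replicate block with an estimated correlation, were chosen after the data were seen. The procedure was tested on simulated data for recovered against acute cells: of 50 genes each, 1 changed 1.5-fold, 17 changed 2-fold, 48 changed 4-fold and 48 changed 8-fold were called, with 2 unchanged genes called. Camera called a raised list of 20 genes and did not call an unchanged list. Genes varied independently in these simulated data, so the preset correlation was not tested. In the real data the estimated correlation was 0.638 for the unfolded protein and integrated stress response list.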

Results

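Gene expression was measured in mouse bone marrow-derived macrophages, cells grown from marrow in a medium that holds macrophage growth factor, on 12 single-colour oligonucleotide arrays. The 4 groups of 3 arrays each were untreated cells, acute cells given lipopolysaccharide (LPS, a bacterial cell wall component) for 4 h, tolerant cells and recovered cells. Tolerant cells had LPS for 8 h, a rest of 16 h and LPS again for 4 h. Recovered cells had the same treatment with a rest of 88 h per the sample descriptions, while the protocol label gives 2 to 4 days. No untreated cells kept for the longer time were analysed here, nor cells given the first LPS and a rest without the second LPS. Between 47.8% and 55.0% of the spots of an array were well above background, and 20469 genes were tested. Arrays of a group correlated with each other at r between 0.980 and 0.994 across genes, and the first principal component held 53.7% of the variance and parted untreated cells from acute and recovered cells, with tolerant cells between them.

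Values are log2 fold changes ± standard error from limma with n = 3 arrays per group, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Where a gene was not well above background on any array of the dimmer group, the change is given as "at least N-fold", the brighter group's mean against the higher of the dimmer group's own signal and the lowest signal well above background. The number of arrays limits the precision of every value. The rule for genes named for the largest changes required no overlap between the arrays of both groups, so its absence lends them no support. Chance gives no overlap for 10% of genes with 3 arrays against 3. Probes of the files' mm9 annotation lay on chromosome 17 at 35336795 to 35336854 for Tnf, chromosome 4 at 88168023 to 88168082 for Ifnb1 and chromosome 10 at 117882841 to 117882900 for Ifng. Those of Mrc1 and Lcn2 lay on chromosome 2 at 14253273 to 14253332 and 32240199 to 32240258, and that of Folr2 on chromosome 7 at 108988771 to 108988830.

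**Figure D1:**
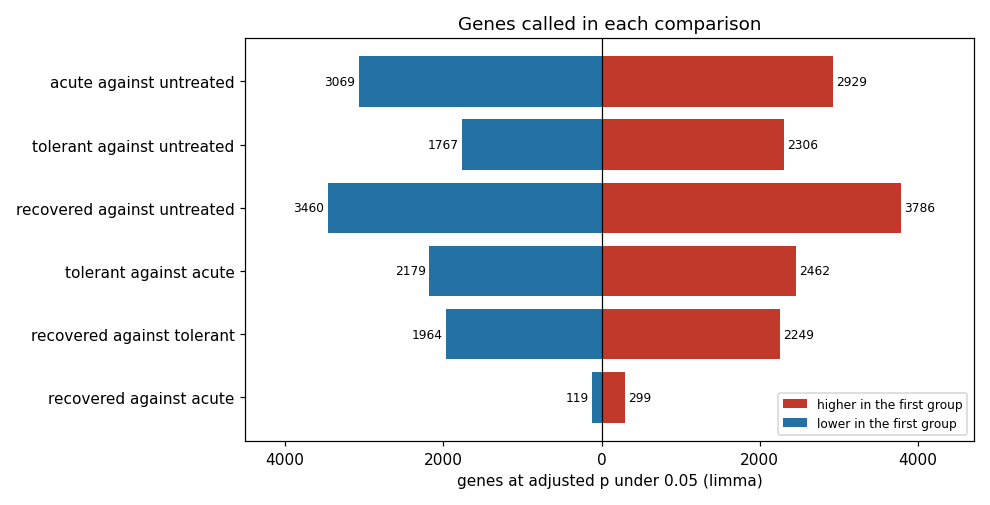
Number of genes called higher or lower (limma, adjusted p under 0.05, n = 3 arrays per group) in each of the 6 comparisons. Bars show genes higher to the right and lower to the left; recovered and acute cells differed in 418 genes, and each of the other comparisons had between 4073 and 7246.

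The comparison of acute with untreated cells describes the first response to LPS. Cytokine transcripts rose: Il6 by 9.95 ± 0.63 (adjusted p = 4.87e-07), Tnf by 4.75 ± 0.23 (adjusted p = 6.84e-08) and Il12b, a subunit of interleukin 12, at least 618-fold (adjusted p = 1.51e-08). Ifnb1, which encodes a type I interferon, rose at least 1036-fold (adjusted p = 1.36e-07), and Cxcl10, a chemokine that interferons induce, rose by 9.91 ± 0.24 (adjusted p = 1.36e-09). Bmf, a gene that promotes cell death, was at least 28.6-fold lower (adjusted p = 6.01e-08), and Sesn1, a stress-response gene, fell by 4.71 on the log2 scale (SE 0.27, adjusted p = 2.32e-07).

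All 44 measured interferon response genes rose in acute cells, with a median of 4.25, among them Rsad2 by 8.01 ± 0.22 and Gbp5 by 8.94 ± 0.23 (44 adjusted over the list alone). Of 18 inflammatory cytokines 17 rose (18 adjusted over the list alone), and of 19 chemokines 16 rose, including Ccl5 by 8.35 ± 0.25. Among 23 antimicrobial and classical effectors 12 rose, such as Ptgs2, which makes prostaglandins, by 7.36 ± 0.47 and Acod1, which makes itaconate, by 6.31 ± 0.21. Camera called each of these 4 lists higher, with adjusted p = 4.08e-46, 1.03e-17, 1.85e-13 and 2.46e-06, and with an estimated correlation their adjusted p was 0.00635, 0.00635, 0.00635 and 0.021. Of 24 feedback inhibitors of toll-like receptor signalling 16 rose and 1 fell, Socs1 by 6.27 ± 0.43 and Socs3 by 4.62 ± 0.13 among the higher (camera adjusted p = 8.6e-09; adjusted p = 0.101 with an estimated correlation). Of 28 TLR4 complex and signalling genes 16 rose and 1 fell, with Nfkb1 higher by 2.50 ± 0.14 (camera adjusted p = 1.1e-05; adjusted p = 0.0725 with an estimated correlation). Of 19 antigen presentation and costimulation genes 9 rose and 1 fell, with Cd40, a costimulatory receptor, higher by 6.32 ± 0.26 (camera adjusted p = 8.29e-05; adjusted p = 0.201 with an estimated correlation). Of 5 measured fibroblast and stromal markers 3 rose, Pdgfrb, a growth factor receptor, at least 9.09-fold and Fbn1, a matrix protein, at least 3.78-fold (camera adjusted p = 0.00642; adjusted p = 0.14 with an estimated correlation). The third of them, Sparc, rose by 0.60 ± 0.20, a call lost without each of the 6 untreated and acute arrays, without tolerant replicate 3 or without recovered replicate 1 (highest adjusted p = 0.125), and also with an intensity trend in the variance prior, no filter on dim probes, normexp background or without the second scan day.

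Camera called none of the other 12 lists in acute against untreated cells, whose lowest adjusted p was 0.142. Proliferation genes went both ways, with 4 of 24 higher, such as Ccne1, a cyclin, by 2.10 ± 0.21, and 9 lower, such as Cdc20, which drives mitotic exit, whose level fell by 1.64 on the log2 scale (list adjusted p = 0.142, called lower with no filter on dim probes). Of 24 macrophage identity genes 2 rose and 2 fell (adjusted p = 0.653), of which Fcgr2b, an inhibitory Fc receptor, rose by 2.26 ± 0.22 and Cebpa, a myeloid transcription factor, fell by 3.12 on the log2 scale. Alternative activation markers (4 of 17 higher, 2 lower, adjusted p = 0.389), glycolysis and hypoxia genes (2 of 22 higher, 2 lower, 0.98), sterol synthesis genes (1 of 22 higher, 4 lower, 0.385) and the unfolded protein and integrated stress response (1 of 18 higher, 1 lower, 0.659) had no called shift. The same held for NRF2 targets (2 of 15 higher, 0.945), neutrophil markers (1 of 6 higher, 0.372), dendritic cell markers (2 of 7 higher, 1 lower, 0.151) and erythroid and platelet markers (1 of 5 lower, 0.385). Of 3 mast cell, basophil and eosinophil markers only Hdc, which makes histamine, was called, at least 152.5-fold higher (list adjusted p = 0.16). Limma called 0 of 5 lymphocyte markers, and 0 had an unadjusted p under 0.05 (list adjusted p = 0.98), but 1 was called lower with either block, with the replicate block Cd79b, a B cell receptor chain (-1.08, SE 0.16, adjusted p = 0.000557). The median and the mean differed in sign for glycolysis (0.01 and -0.02), NRF2 targets (-0.09 and 0.09, camera up) and lymphocyte markers (0.10 and -0.13, camera up).

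In all, 5998 genes were called between acute and untreated cells, 2929 higher and 3069 lower. The share of higher genes was 48.8%, and it was 37.3% with the authors' values. With the slide as a block 9304 genes were called.

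The comparison of tolerant with untreated cells shows how cells differed from resting cells after both LPS exposures and the short rest. The first exposure, the second exposure and the time in culture cannot be told apart in it. Il6 was higher by 7.67 ± 0.63 (adjusted p = 9.02e-06), Il1b, another cytokine, by 7.98 ± 0.39 (adjusted p = 1.82e-07) and Ccl5 by 8.41 ± 0.25 (adjusted p = 6.01e-09). Adamts4, a protease of the cell matrix, was at least 73-fold higher (adjusted p = 1.02e-08). Mgll, which breaks down monoacylglycerols, fell by 3.86 on the log2 scale (SE 0.20, adjusted p = 2.75e-07), and Dio2, which activates thyroid hormone, fell by 4.11 (SE 0.46, adjusted p = 8.98e-05). Mrc1, the mannose receptor, fell by 1.78 (SE 0.19, adjusted p = 7.88e-05), and Lcn2, an iron-binding antimicrobial protein, rose by 4.44 ± 0.71 (adjusted p = 0.00107), a call lost with the authors' values (5.74, adjusted p = 0.115).

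All 44 interferon response genes were higher in tolerant than in untreated cells (44 adjusted over the list alone), with Oasl1 up by 6.22 ± 0.26, as were 16 of 18 cytokines, 16 of 19 chemokines and 16 of 23 antimicrobial effectors, the last with Saa3, an acute-phase protein, up by 5.68 ± 0.35. Camera gave adjusted p = 2.42e-49, 1.71e-18, 3.68e-16 and 2.9e-13 for these 4 lists, and 0.00385, 0.00385, 0.00337 and 0.00337 with an estimated correlation. Of 24 feedback inhibitors 14 were higher, Socs3 by 4.99 ± 0.13 among them, of 28 TLR4 signalling genes 12 were higher, and of 19 antigen presentation genes 9 were higher and 1 lower (11 and 1 adjusted over the list alone). Camera called these 3 lists (2.05e-07, 3.85e-06 and 1.71e-07), and their adjusted p = 0.115, 0.0639 and 0.102 with an estimated correlation. Of 24 proliferation genes 15 were lower and 0 higher (18 and 2 adjusted over the list alone), with the cyclin gene Ccnb2 falling by 1.89 on the log2 scale (SE 0.28) and Bub1b by 1.86 (SE 0.26). Camera called them lower (adjusted p = 7.29e-07; adjusted p = 0.24 with an estimated correlation). Of 22 glycolysis and hypoxia genes 13 were higher, with Slc16a3, a lactate exporter, up by 2.56 ± 0.17 (adjusted p = 3.85e-06; adjusted p = 0.106 with an estimated correlation). Of 22 sterol synthesis genes 6 were higher (12 adjusted over the list alone), with Idi1, an isoprenoid enzyme, up by 1.55 ± 0.24 (adjusted p = 0.000307; adjusted p = 0.31 with an estimated correlation). NRF2 targets had 4 of 15 higher and 1 lower, with Slc7a11, a cystine transporter, up by 2.65 ± 0.34 (adjusted p = 0.00503; adjusted p = 0.188 with an estimated correlation).

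The unfolded protein and integrated stress response list was called lower in tolerant than untreated cells, with 5 of 18 lower and 1 higher (adjusted p = 0.049; adjusted p = 0.617 with an estimated correlation). Its member Phgdh, an enzyme of serine synthesis, fell by 3.90 on the log2 scale (SE 0.80). Of 7 dendritic cell markers 4 rose and 1 fell, with Fscn1, an actin-bundling protein, up by 4.94 ± 0.33, and camera called the list (adjusted p = 0.0283; adjusted p = 0.15 with an estimated correlation). That list's call was lost with the replicate block (0.115), the slide block (0.118), no filter on dim probes and without the second scan day (0.0572). Of 5 stromal markers Pdgfrb was called, at least 20.8-fold higher (list adjusted p = 0.00697; adjusted p = 0.13 with an estimated correlation). The median, the mean and camera differed in sign for alternative activation markers (-0.41, -0.08 and up, adjusted p = 0.888), of which 6 of 17 were higher and 4 lower. They also differed for macrophage identity (-0.09, 0.07 and up, 0.797), mast cell markers (-0.02, 1.69 and up, 0.104, called with no filter on dim probes) and erythroid and platelet markers (-0.24, 0.13 and down, 0.889).

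Between tolerant and untreated cells 4073 genes were called, 2306 higher and 1767 lower, and the replicate block called 7679 and the slide block 8073. The share of higher genes, 56.6%, was 45.5% with quantile normalization and 40.9% with the authors' values.

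The comparison of recovered with untreated cells shows how cells differed from resting cells after both LPS exposures and the longer rest. Here too, both exposures and the time in culture cannot be told apart. Il6 was higher by 10.02 ± 0.63 (adjusted p = 4.55e-07), Tnf by 4.80 ± 0.23 (adjusted p = 5.92e-08), Cxcl10 by 9.96 ± 0.24 (adjusted p = 9.04e-10) and Ifnb1 at least 316-fold (adjusted p = 4.47e-07). Folr2, a folate receptor of macrophages, rose by 2.51 ± 0.34 (adjusted p = 0.000144), and Msr1, a scavenger receptor, by 2.85 ± 0.16 (adjusted p = 1.7e-07). Chac1, which degrades glutathione, fell by 5.76 on the log2 scale (SE 1.12, adjusted p = 0.0019), and Trib3, a pseudokinase that stress induces, fell by 5.57 (SE 1.10, adjusted p = 0.00219).

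All 44 interferon response genes were higher in recovered than untreated cells, Mx1 by 7.84 ± 0.22, as were 17 of 18 cytokines, 17 of 19 chemokines and 14 of 23 antimicrobial effectors (44, 17, 17 and 15 adjusted over the list alone). Camera gave adjusted p = 7.71e-39, 7.61e-15, 3.86e-13 and 4.67e-07, and 0.0109, 0.0109, 0.00993 and 0.0142 with an estimated correlation. Feedback inhibitors (15 of 24 higher, 1 lower, camera adjusted p = 2.44e-06), TLR4 signalling genes (18 of 28 higher, 1 lower, 7.2e-05) and antigen presentation genes (10 of 19 higher, 1 lower, 7.2e-05) were called higher too, with Cd14, a co-receptor for LPS, up by 1.97 ± 0.14. Those lists had adjusted p = 0.154, 0.108 and 0.175 with an estimated correlation. Of 17 alternative activation markers 9 rose and 2 fell (10 and 2 adjusted over the list alone), and camera called the list higher (adjusted p = 0.0154; adjusted p = 0.154 with an estimated correlation). Among those that fell was Egr2, a transcription factor, by 2.60 on the log2 scale (SE 0.41). Of 24 macrophage identity genes 11 rose and 1 fell, with Fcgr2b up by 3.21 ± 0.22 and C1qa, a complement component, by 1.02 ± 0.17 (adjusted p = 0.0133; adjusted p = 0.185 with an estimated correlation). That call was lost with quantile normalization (0.225). Of 18 stress response genes 9 were lower and 1 higher (adjusted p = 0.0152; adjusted p = 0.608 with an estimated correlation). Of 5 stromal markers 3 were higher, Pdgfrb at least 23.6-fold (adjusted p = 0.00652; adjusted p = 0.154 with an estimated correlation). Proliferation genes (4 of 24 higher, 7 lower, adjusted p = 0.196) were called lower as a list with no filter on dim probes alone. The median and mean differed in sign for NRF2 targets (-0.19 and 0.11, camera down, adjusted p = 0.953) and lymphocyte markers (0.22 and -0.56, camera down, 0.971), of which Cd79b, a B cell receptor component, fell by 3.86 on the log2 scale (SE 0.65).

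In this comparison 7246 genes were called, 3786 higher and 3460 lower. The share of higher genes, 52.2%, was 39.9% with quantile normalization and 38.9% with the authors' values. Over all genes, the median log2 fold change of recovered against untreated cells was 0.06, and -0.08 with quantile normalization and -0.08 with the authors' values, and that of acute against untreated cells was 0.02, -0.12 and -0.09.

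The comparison of tolerant with acute cells asks how cells after a second LPS exposure differed from cells after a first. What remained of the first exposure cannot be told apart from a changed response to the second. Ifnb1 fell by 5.08 on the log2 scale (SE 0.63, adjusted p = 0.000304), and Il33, a cytokine of the interleukin 1 family, was at least 24.5-fold lower (adjusted p = 9.19e-05). Tnf fell by 2.03 (SE 0.23, adjusted p = 0.000189) and Cxcl10 by 1.57 (SE 0.24, adjusted p = 0.00111). With the authors' values they fell by 1.68 and 1.24 without a call (adjusted p = 0.623 and 0.728), in a fit whose shared variance held untreated array 3 at 2.58 for both genes. Il10, an anti-inflammatory cytokine, fell by 2.24 (SE 0.41, adjusted p = 0.00285) and Mrc1 by 1.95 (SE 0.19, adjusted p = 9.19e-05). Other genes were higher: Ly6a, a surface protein of progenitors, by 4.95 ± 0.51 (adjusted p = 0.000113), Cx3cr1, the fractalkine receptor, by 4.43 ± 0.50 (adjusted p = 0.000176) and Csf2, a growth factor for myeloid cells that was well above background on 2 of the 3 acute arrays, by 2.78 ± 0.38 (adjusted p = 0.000536).

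Of 44 interferon response genes 36 were lower in tolerant than acute cells and 0 higher (37 and 0 adjusted over the list alone), with a median of -1.48 (camera adjusted p = 2.71e-21; adjusted p = 0.179 with an estimated correlation). Of 18 cytokines 10 were lower and 2 higher (adjusted p = 0.00146; adjusted p = 0.48 with an estimated correlation), with Tnfsf15 falling by 2.66 (SE 0.41). Feedback inhibitors had 9 of 24 lower and 2 higher (adjusted p = 0.0173; adjusted p = 0.507 with an estimated correlation), among them Cish, an inhibitor of cytokine signalling, which fell by 3.39 (SE 0.33). Of 24 proliferation genes 10 were lower (adjusted p = 0.000235; adjusted p = 0.507 with an estimated correlation), such as Ccnb2, by 1.61 (SE 0.28). Glycolysis and hypoxia genes were higher for 11 of 22 and lower for 1, with Slc16a3 up by 2.57 ± 0.17 and Pfkl, a glycolytic enzyme, by 2.11 ± 0.24 (adjusted p = 3.28e-05; adjusted p = 0.444 with an estimated correlation). Sterol synthesis genes were higher for 11 of 22 (14 adjusted over the list alone), with Sqle up by 1.16 ± 0.24 (adjusted p = 1.45e-05; adjusted p = 0.488 with an estimated correlation). NRF2 targets were higher for 4 of 15, with Gclm, an enzyme of glutathione synthesis, up by 1.29 ± 0.28 (adjusted p = 0.0173; adjusted p = 0.488 with an estimated correlation). Chemokines (7 of 19 lower, 2 higher, adjusted p = 0.0826) and antimicrobial effectors (2 of 23 lower, 7 higher, 0.239) were not called as lists, though chemokines were called lower with no filter on dim probes. Saa3 was higher by 3.37 ± 0.35, Cxcl3 by 2.15 ± 0.39 and Lcn2 by 3.87 ± 0.71, calls lost with the authors' values (Saa3 3.20, Cxcl3 2.33 and Lcn2 6.01). Signs differed for alternative activation markers (median 0.03, mean -0.31, camera down, adjusted p = 0.88), macrophage identity (-0.12, 0.01 and up, 0.983) and dendritic cell markers (-0.09, 0.29 and up, 0.655).

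Between tolerant and acute cells 4641 genes were called, 2462 higher and 2179 lower. With the replicate block 9107 genes were called, and 9612 with the slide block, and without tolerant replicate 2 the genes higher in tolerant cells were 1610. Of the 1989 LPS-induced genes (called and at least 2-fold higher in acute than untreated cells), 1109 were lower in tolerant than acute cells, 53 higher and 827 not called. The 53 were 123 without tolerant replicate 1, 102 with the replicate block and 35 with the authors' values. The 827 were 509 of 2101 induced genes with the replicate block, 500 of 2102 with the slide block, 519 of 1497 with normexp background and 518 of 1518 with the authors' values. The 1109 are called tolerised here. Simulated tolerant cells equal to acute cells gave 0 on average over 20 simulations, which hold no differences between experiments. Every gene was equal in both groups there, so a count near 0 was set in advance. It does not measure what the shared arrays add. Independent lists would share 211.7. Part of the excess may come from the acute arrays that both comparisons share, since 3 arrays cannot be split with at least 2 in each part.

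The comparison of recovered with tolerant cells asks how cells differed between the longer and the short rest. A changed response to the second exposure, levels already changed before it and the time in culture cannot be told apart in it. Mycl, a Myc family transcription factor, was at least 13.1-fold higher (adjusted p = 1.84e-05) and Inhbb, an activin subunit, at least 13-fold higher (adjusted p = 5.49e-05) in recovered cells. Mrc1 rose by 2.82 ± 0.19 (adjusted p = 2.61e-05) and Ifnb1 by 3.37 ± 0.63 (adjusted p = 0.0042). Ifng, the type II interferon, was at least 7.11-fold higher (adjusted p = 0.00297). Tnf rose by 2.08 ± 0.23 (adjusted p = 0.000249) and Cxcl10 by 1.61 ± 0.24 (adjusted p = 0.00128). With the authors' values they rose by 1.67 and 1.19 without a call, again with untreated array 3 at 2.58 in the shared variance. Bmf was at least 6.57-fold lower (adjusted p = 1.84e-05), and Csf2, well above background on 2 of the 3 recovered arrays, fell by 2.44 on the log2 scale (SE 0.38, adjusted p = 0.00153).

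Of 44 interferon response genes 36 were higher in recovered than tolerant cells and 0 lower (39 and 0 adjusted over the list alone), with a median of 1.47 (camera adjusted p = 1.88e-21; adjusted p = 0.161 with an estimated correlation). Cytokines (10 of 18 higher, 1 lower, adjusted p = 0.000128), chemokines (9 of 19 higher, 0.00224) and alternative activation markers (7 of 17 higher, 0.00422) were called higher, each with adjusted p = 0.161 with an estimated correlation. Tnfsf15 rose by 2.62 ± 0.41 and Folr2 by 2.30 ± 0.34. Proliferation genes were higher for 9 of 24 (12 adjusted over the list alone), Ccnb2 by 2.01 ± 0.28 and Plk1, a mitotic kinase, by 1.56 ± 0.26 (adjusted p = 0.000128; adjusted p = 0.407 with an estimated correlation). Macrophage identity genes were higher for 7 of 24 and lower for 2, with Trem2, a lipid-sensing receptor, up by 1.01 ± 0.17 (adjusted p = 0.005; adjusted p = 0.192 with an estimated correlation), a list call lost with quantile normalization (0.172). Glycolysis and hypoxia genes were lower for 10 of 22 and higher for 1 (adjusted p = 0.000128; adjusted p = 0.188 with an estimated correlation), and Bnip3, a mitochondrial protein that hypoxia induces, fell by 1.23 (SE 0.23). Sterol synthesis genes were lower for 3 of 22 and higher for 1 (adjusted p = 0.0153; adjusted p = 0.511 with an estimated correlation). NRF2 targets were lower for 2 of 15, Gclm falling by 1.22 (SE 0.28) (adjusted p = 0.00422; adjusted p = 0.223 with an estimated correlation). Erythroid and platelet markers were lower for 3 of 5 (adjusted p = 0.0299; adjusted p = 0.161 with an estimated correlation), with Epor, the erythropoietin receptor, falling by 1.54 (SE 0.25). Their list call was lost with the replicate block (0.0616), quantile normalization (0.0685), normexp background and no filter on dim probes. Feedback inhibitors (8 of 24 higher, 1 lower, adjusted p = 0.0549) were called higher with the slide block (0.0332). TLR4 signalling genes (9 of 28 higher, 2 lower, 0.0805) were called with the slide block (0.0388) and with no filter on dim probes, and the stress response list (2 of 18 higher, 2 lower, 0.31) was called lower without the second scan day (0.0444). Signs differed for antimicrobial effectors (median 0.12, mean -0.02, camera up, adjusted p = 0.906), dendritic cell markers (0.08, -0.08 and down, 0.765) and lymphocyte markers (0.37, -0.16 and up, 0.584).

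Between recovered and tolerant cells 4213 genes were called, 2249 higher and 1964 lower. The share of higher genes, 53.4%, was 42.2% with the authors' values. The replicate block called 9233 and the slide block 8236, and the count was 2712 without tolerant replicate 1, 2768 without tolerant replicate 2, 2579 without recovered replicate 1 and 2768 without recovered replicate 3. The 2249 higher genes were 1442 without tolerant replicate 1 and 1369 without recovered replicate 1, and the 1964 lower genes were 1270, 1175, 1210 and 1257 without tolerant replicates 1 and 2 and recovered replicates 1 and 3. Of the 1109 tolerised genes 891 were higher in recovered than tolerant cells and 218 were not called, which became 133 without acute replicate 1 and 362 without recovered replicate 1. Limma called 0 lower, with 0 at an unadjusted p under 0.05, while 3 were called lower with the replicate block, 4 without the second scan day and 1 without recovered replicate 1. Simulated recovered cells equal to tolerant cells gave 0 of them higher on average, again a count near 0 set in advance. Independent lists would share 121.8. Part of the excess may come from the shared tolerant arrays. Of the 891, 878 were not called between recovered and acute cells, 10 were lower and 3 higher. With the replicate block 105 of 1283 were lower and 29 higher, and with the slide block 58 of 1271 and 26. With the authors' values they were 28 of 790 and 2, without the second scan day 20 of 876 and 4, and without single arrays 0 to 20 and 0 to 4.

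**Figure D2:**
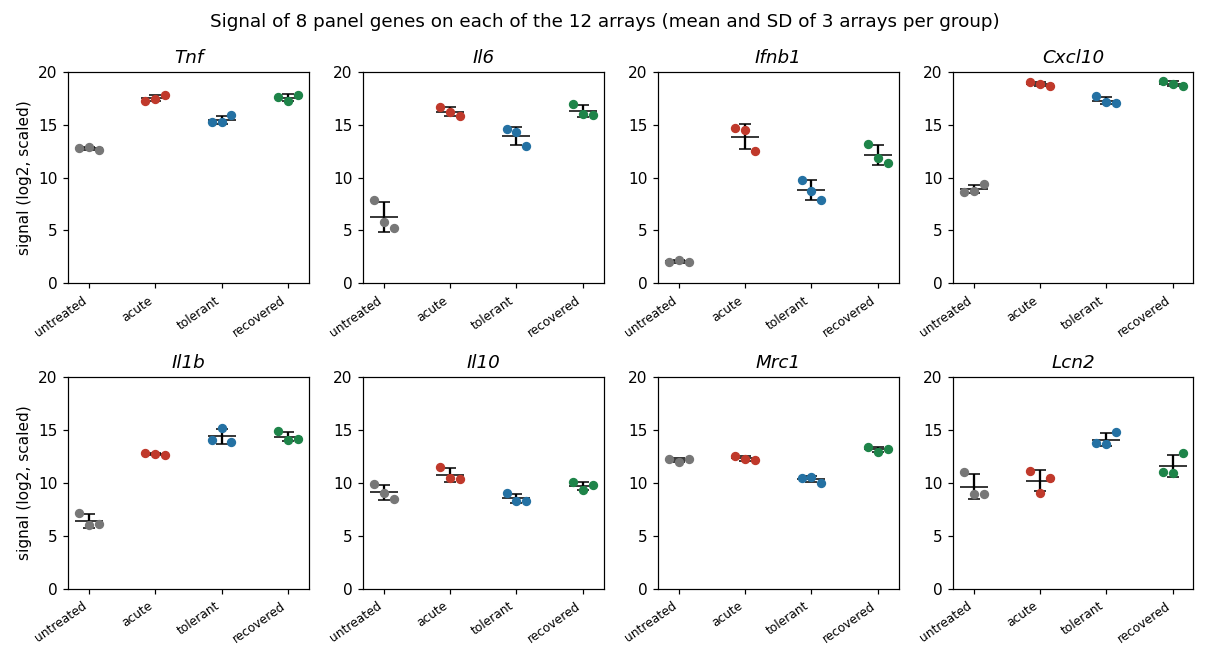
Log2 scaled signal of 8 genes of the fixed panel in untreated, acute, tolerant and recovered cells, as points for the 3 arrays of a group with the mean and standard deviation. Tnf lay at 17.51 in acute, 15.48 in tolerant and 17.55 in recovered cells, and Mrc1 at 12.31, 10.36 and 13.18.

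The comparison of recovered with acute cells asks how cells after a second LPS exposure and the longer rest differed from cells after a first exposure. A changed response to LPS, what remained of the first exposure and the time in culture cannot be told apart in it. Ctla2a, an inhibitor of cysteine proteases, was higher by 3.54 ± 0.34 (adjusted p = 0.00191) and Slc16a3 by 1.53 ± 0.17 (adjusted p = 0.00496), while Cdkn1c, an inhibitor of cell division, fell by 2.93 on the log2 scale (SE 0.32, adjusted p = 0.00388). These 3 calls held without each array in turn and under every other setting run. Saa3 was higher by 2.55 ± 0.35 (adjusted p = 0.0101) and Fscn1 by 2.78 ± 0.33 (adjusted p = 0.00542), calls lost with the authors' values (2.24 and 2.56). Ripor2 was at least 1.44-fold lower (adjusted p = 0.00108), a call lost with normexp background. Panel genes with no call included Tnf (0.05 ± 0.23, adjusted p = 0.949), Il6 (0.07 ± 0.63, 0.975), Cxcl10 (0.04 ± 0.24, 0.961) and Nos2 (0.19 ± 0.33, 0.851). Il1b (1.65 ± 0.39, adjusted p = 0.0562), Ifnb1 (-1.71 ± 0.63, 0.234), Il10 (-1.05 ± 0.41, 0.263) and Cd86, a costimulatory ligand (-1.79 ± 0.59, 0.176), were called with the replicate block, at adjusted p = 0.0215, 0.0283, 0.0129 and 0.00722.

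Of 17 alternative activation markers 5 were higher in recovered than acute cells and 0 lower (7 and 0 adjusted over the list alone), and the list had adjusted p = 0.00013 (adjusted p = 0.0917 with an estimated correlation). Tgm2, a transglutaminase, rose by 1.05 ± 0.14 (adjusted p = 0.0101), a call lost without acute replicate 2 (0.0561), and Msr1 by 1.16 ± 0.16 (adjusted p = 0.0101), lost without acute replicate 2 or recovered replicate 1 (highest 0.0561). Folr2 rose by 2.14 ± 0.34 (adjusted p = 0.016), lost without acute replicate 1 or 2 or recovered replicate 1 or 2 (highest 0.0791). Mrc1 rose by 0.87 ± 0.19 (adjusted p = 0.0489), lost without 11 of the 12 arrays, all but tolerant replicate 3, with a highest adjusted p of 0.176, and with the authors' values, no filter on dim probes or without the second scan day. Of 24 macrophage identity genes 4 were higher (7 adjusted over the list alone), C1qa, C1qb, Csf1r and Trem2 (list adjusted p = 1.23e-05; adjusted p = 0.0917 with an estimated correlation). All 4 calls were lost with no filter on dim probes and without untreated replicate 2, acute replicate 1 or 2, or any recovered replicate (highest adjusted p from 0.123 to 0.172). Csf1r and Trem2 were also lost without acute replicate 3, C1qb, Csf1r and Trem2 without tolerant replicate 2, C1qb and Trem2 without tolerant replicate 1, C1qb without untreated replicate 1 and Trem2 without tolerant replicate 3. C1qb, Csf1r and Trem2 were lost with quantile normalization, and Csf1r with the mean of its probes. Antimicrobial effectors were higher for 2 of 23 (adjusted p = 0.00432; adjusted p = 0.213 with an estimated correlation). The stress response list was lower with 1 of 18 called (adjusted p = 4.92e-05; adjusted p = 0.565 with an estimated correlation), Chac1, which fell by 5.27 (SE 1.12, adjusted p = 0.042), a call lost without untreated replicate 2, acute replicates 1 and 2, tolerant replicate 2 and each recovered replicate, and with no filter on dim probes or normexp background. Sterol synthesis genes were called higher as a list (adjusted p = 0.00013; adjusted p = 0.565 with an estimated correlation), with 0 of 22 called by limma, 8 at an unadjusted p under 0.05, 4 adjusted over the list alone and 5 called with the replicate block, and the list was not called without the second scan day (0.119).

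Limma called 0 of 44 interferon response genes between recovered and acute cells, with 3 at an unadjusted p under 0.05 (list median -0.05, adjusted p = 0.46), and the list was called lower with normexp background. It also called 0 of 28 TLR4 signalling genes (3 unadjusted, list 0.679), 0 of 19 antigen presentation genes (2 unadjusted, 0.446), 0 of 24 proliferation genes (1 unadjusted, 0.721) and 0 of 15 NRF2 targets (1 unadjusted, 0.721). The count was 0 of 5 for lymphocyte markers (1 unadjusted, 0.763) and 0 of 3 for mast cell markers (0 unadjusted, 0.596). With the replicate block 1 interferon response gene was higher and 1 lower, 2 TLR4 signalling genes were higher, 2 antigen presentation genes were higher and 1 lower, and 1 NRF2 target and 1 lymphocyte marker were lower. Without the second scan day 1 antigen presentation gene and 1 lymphocyte marker were lower and 1 NRF2 target was higher. Chemokines had 2 of 19 higher (list 0.173), cytokines 1 of 18 lower (0.776), glycolysis genes 3 of 22 higher (0.111) and feedback inhibitors 1 of 24 higher and 1 lower (0.128). Dendritic cell markers had 1 of 7 higher and 1 lower (0.721), stromal markers 1 of 5 higher (0.177), neutrophil markers 1 of 6 lower (0.803) and erythroid and platelet markers 1 of 5 lower (0.111). With the slide block, camera called chemokines (0.0163) and antigen presentation genes (0.0163) higher, and feedback inhibitors were called lower without the second scan day (0.018), with normexp background and with no filter on dim probes. Signs differed for NRF2 targets (median 0.03, mean 0.02, camera down), neutrophil markers (0.16, -0.34 and down) and lymphocyte markers (0.11, -0.43 and down).

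**Figure D3:**
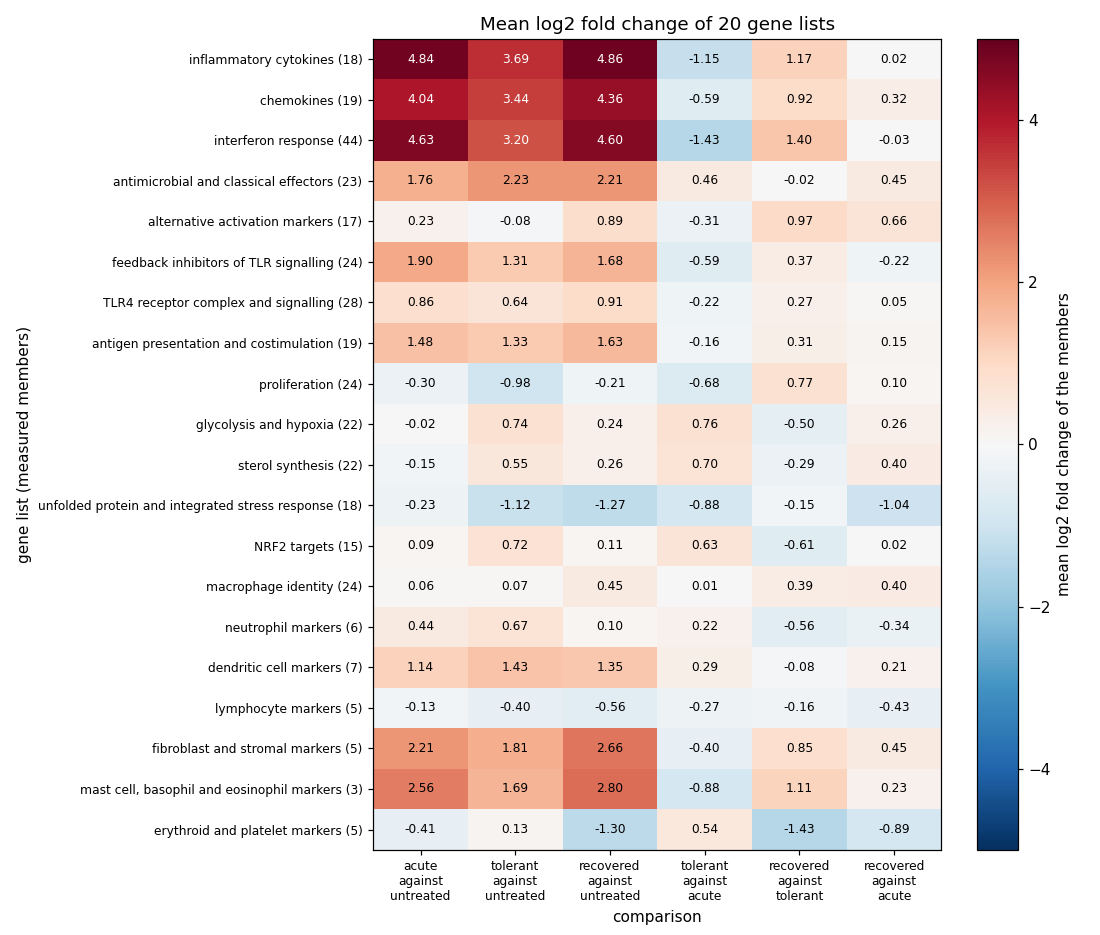
Mean log2 fold change of the measured members of each of the 20 gene lists (vertical axis) in each of the 6 comparisons (horizontal axis), on a colour scale from lower to higher. Interferon response genes had a mean of 4.63 in acute against untreated, -1.43 in tolerant against acute and -0.03 in recovered against acute cells.

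Between recovered and acute cells 418 genes were called, 299 higher and 119 lower. The share of higher genes, 71.5%, was 60.8% with quantile normalization and 49.9% with the authors' values. Without the second scan day the balance turned, with 249 genes higher and 330 lower, and without acute replicate 3 there were 199 higher and 203 lower. The replicate block called 2199 genes, 1226 higher and 973 lower, and the slide block 1600, 930 higher and 670 lower. The count was 174 without untreated replicate 2, 49 and 25 without acute replicates 1 and 2, 195 without tolerant replicate 2, and 48, 53 and 106 without recovered replicates 1, 2 and 3. It was 196 with only the groups of the comparison, which ended 26 of the 52 calls of named genes, 99 with no filter on dim probes and 1195 with the authors' values.

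Of the 1989 LPS-induced genes 23 were lower in recovered than acute cells, 108 higher and 1858 not called. Il33, well above background on 2 of the 3 recovered arrays, fell by 4.27 on the log2 scale (SE 0.67, adjusted p = 0.016), a call lost without acute replicate 1 or 2 or recovered replicate 2 or 3 (highest 0.0791). Hal, which breaks down histidine, fell by 1.95 (SE 0.33, adjusted p = 0.0216), a call lost without acute replicate 1 or 2 or any recovered replicate, with no filter on dim probes and without the second scan day. Simulated recovered cells equal to acute cells gave 0.1 lower and 0 higher genes on average, counts near 0 that this setting gives in advance. Independent lists would share 11.6 and 29.1. Part of the excess may come from the shared acute arrays. The 108 higher genes became 244 with the replicate block, 224 with the slide block, 54 without the second scan day, 41 with quantile normalization, 29 of 1518 induced genes with the authors' values and 19 with no filter on dim probes. They were 46 and 35 without untreated replicates 1 and 2, 11, 8 and 44 without acute replicates 1, 2 and 3, 34 without tolerant replicate 2, and 10, 13 and 18 without recovered replicates 1, 2 and 3. The 23 lower genes became 201 with the replicate block, 128 with the slide block, 72 without the second scan day, 89 with the authors' values and 7 with no filter on dim probes. Leaving out single arrays gave 7 without untreated replicate 2, 2, 0 and 60 without acute replicates 1, 2 and 3, 12 without tolerant replicate 2, and 5, 2 and 5 without recovered replicates 1, 2 and 3. More induced genes were lower than higher in recovered cells without the second scan day (72 and 54), without acute replicate 3 (60 and 44) and with the authors' values (89 and 29).

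In recovered cells 85 genes were higher than in both acute and tolerant cells, and 42 were lower than in both. Mycl was higher than in acute cells by 1.83 ± 0.29 (adjusted p = 0.016), a call lost without acute replicate 1 or 2 or recovered replicate 1 or 2 (highest 0.0761) and with the authors' values. Ifng was called higher than in acute cells (adjusted p = 0.0389), with no exact fold given since it was well above background on 1 of the 3 acute arrays, a call lost without untreated replicates 1 and 2, acute replicates 1 and 2 and each recovered replicate (highest 0.134), and with quantile normalization or no filter on dim probes. It was well above background on 3 recovered arrays, 1 acute array and no other array. Batf3, a transcription factor, fell against tolerant cells by 1.78 (SE 0.37, adjusted p = 0.0068) and against acute cells by 1.90 (SE 0.37, adjusted p = 0.0333), the latter lost without untreated replicate 2, acute replicates 1 and 2 and each recovered replicate (highest 0.127) and with no filter on dim probes. Simulated groups without that difference gave 0 of each, as that setting gives in advance. Independent lists would share 32.9 and 11.4. Part of the excess may come from the shared recovered arrays.

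The 85 genes became 535 with the replicate block, 376 with the slide block and 24 with no filter on dim probes. The 42 became 415, 304 and 11, and 128 without the second scan day. With the authors' values the counts were 183 and 238. Without untreated replicate 2 the 85 and 42 were 42 and 23, without acute replicates 1 and 2 they were 12 and 6, and 7 and 2. Without tolerant replicates 1 and 3 the 85 were 47 and 136, and without tolerant replicate 2 both counts were 35 and 25. Without recovered replicates 1, 2 and 3 they were 11 and 6, 10 and 10, and 22 and 18.

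Of the 299 genes higher in recovered than acute cells, 134 were also called higher in tolerant than acute cells, 8 lower and 157 not called, with medians of 1.37 and 0.69. Of the 119 lower genes 61 were also lower, 5 higher and 53 not called, with medians of -1.35 and -0.80. Among all 20469 genes tested, 2462 were higher and 2179 lower in tolerant than acute cells. The acute arrays enter both comparisons, so part of these overlaps may come from them. Ly6a, higher by 4.95 ± 0.51 in tolerant cells, was higher by 3.22 ± 0.51 in recovered cells (adjusted p = 0.0181), a call lost without acute replicate 1 or 2 or recovered replicate 1 or 2 (highest 0.0835), with the authors' values and without the second scan day. Across all genes the fold changes of tolerant and recovered against acute cells had a covariance of 0.143, against 0.04 in simulations without a difference, and a correlation of 0.418, against 0.50, where genes are not independent replicates.

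Levels of further panel genes are given as mean ± standard deviation of the log2 scaled signal (n = 3 arrays). Lcn2 lay at 9.64 ± 1.19 in untreated, 10.22 ± 1.04 in acute, 14.09 ± 0.64 in tolerant and 11.59 ± 1.07 in recovered cells, and its difference between recovered and untreated cells (adjusted p = 0.0517) was called with the replicate block (0.0231). Marco, a scavenger receptor, lay at 18.11 ± 0.12, 18.29 ± 0.09, 18.57 ± 0.35 and 17.43 ± 0.79, and its fall between tolerant and recovered cells (adjusted p = 0.0298) was not called without tolerant replicate 1 or 2 (highest 0.0971) or with no filter on dim probes. Irak3, an inhibitor of TLR signalling, lay at 12.61 ± 0.19, 12.75 ± 0.02, 13.23 ± 0.34 and 13.25 ± 0.09, and its higher level in tolerant than untreated cells (adjusted p = 0.03) was not called without untreated replicate 2 or 3 or tolerant replicate 2 or 3 (highest 0.104), nor with no filter on dim probes, quantile normalization or without the second scan day. Tlr4, the LPS receptor, lay at 11.02 ± 0.24, 11.67 ± 0.48, 10.63 ± 0.38 and 11.38 ± 0.25, and only the fall between acute and tolerant cells was called (adjusted p = 0.0163), a call lost without acute replicate 1 or 2 or tolerant replicate 3 (highest 0.0622). With the replicate block Tlr4 was also called in acute (0.00241), tolerant (0.0382) and recovered cells (0.0365) against untreated cells and between recovered and tolerant cells (0.00174). Tnfaip3 and Ccl2 rose in acute cells by 3.36 ± 0.19 and 5.07 ± 0.45. Arg1, an enzyme of alternative activation, was above background on 2 tolerant arrays alone and was not tested.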

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

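Leaving out the second scan day and combining the replicate block with an estimated correlation were chosen after the result was seen, as were all settings for the genes apart in tolerant cells; the other settings were planned. Calls of the main analysis had the opposite direction in 0 genes with the replicate block, slide block, quantile normalization or no filter on dim probes, in 1 gene with normexp background and 1 with the authors' values (both in recovered against untreated cells), and in up to 7 genes per comparison with the mean of a gene's probes. The proliferation gene Ttk, well above background on no recovered array and at least 1.55-fold lower in recovered than untreated cells, lost its call with normexp background, with a value near 0 and of the other sign (0.034, adjusted p = 0.898); the call was also lost with quantile normalization, no filter on dim probes, the intensity trend, without the second scan day and without 6 of the 12 arrays (highest 0.167), and the cause was not tested. With the replicate block, the counts were 7679 (tolerant against untreated), 9107 (tolerant against acute), 9233 (recovered against tolerant), 2199 (recovered against acute) and 13680 (any difference among the groups). LPS-induced genes lower in recovered than acute cells numbered 201, and genes higher and lower in recovered than both others 535 and 415. Among named genes this block ended 0 calls and gave 22 more, and it ended the calls of 2 lists. With the slide block the counts were 9304 (acute against untreated), 8073, 9612, 8236, 1600 and 13505, and 128, 376 and 304 for the 3 sets. With the authors' values they were 9324, 7086, 11152, 7675, 7426, 1195 and 12921, and 89, 183 and 238 for the sets, and 84 named calls were lost, each with its direction kept. With no filter on dim probes recovered and acute cells differed in 99 genes, and the sets held 7, 24 and 11. With a 2-fold threshold, which can only remove genes, the counts were 3578, 2257, 4170, 2120 and 1809. With only the groups of the comparison, which leaves 6 arrays, recovered and acute cells differed in 196 genes, and 26 of 52 named calls between them were lost, against 1 to 7 per comparison in the others, a test of single genes that was chosen after the counts were seen. Without the second scan day, 72 induced genes were lower in recovered than acute cells and 128 genes were lower than in both others. Apart from the smaller numbers of genes or arrays named, the cause of these shifts was not tested. Leaving out single arrays gave 25 to 446 genes for recovered against acute cells and 2579 to 4510 for recovered against tolerant cells. The induced genes lower in recovered cells ranged from 0 to 60, the genes higher than both from 7 to 136 and those lower than both from 2 to 62. The totals called in the other 4 comparisons and among the 4 groups, the induced genes lower in tolerant cells and the tolerised genes higher in recovered cells stayed within 1.5 times the main count without each array. Counts by direction and of other parts of these sets moved further in 53 leave-one-out values and stayed within it in 223. Of the named calls, 46 of 52 between recovered and acute cells were lost without some array, against 27 of 96 between recovered and tolerant cells, 14 of 85 between tolerant and acute cells, and 5 of 77, 11 of 79 and 4 of 82 in acute, tolerant and recovered against untreated cells. Where a group had no signal above background, the fold is a lower limit, and changes among genes below background on all groups were not measurable.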

Other observations

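The tests of stromal cells or lymphocytes and both tests of the authors' matrix were chosen only after the result was seen. The bounds of the stromal and faint-spot tests were set again once their counts were known. Both are therefore treated as undecided over their full sets. Scanner flags of the faint-spot test are read only for the spots that they call well above background. In tolerant cells 1427 genes were higher and 1413 lower than in both acute and recovered cells, counts chosen after the data were seen. Simulated groups without a difference gave 0 of each, as that setting gives in advance. Independent lists would share 236.2 and 239.4, so part of the excess may come from the shared tolerant arrays. The simulations held no experiment effect. The counts were 2972 and 3191 with the replicate block, 2866 and 3287 with the slide block and 3102 and 2010 with the authors' values, and the 1427 were 945 without recovered replicate 1 and 853 without tolerant replicate 2. Of the 1427, 1014 were lower in acute than untreated cells, and against untreated cells 303 were higher in tolerant cells, 212 lower and 912 not called. Bmf, a gene that promotes cell death, was at least 8.03-fold higher in tolerant than acute cells and at least 6.57-fold lower in recovered than tolerant cells, and Adgrg1, an adhesion receptor, at least 7.66-fold and at least 6.27-fold.

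Of 2752 lincRNA loci, 325 were higher and 157 lower in acute than untreated cells (17.5% called, against 31.1% of other genes), and 548 and 188 in recovered against untreated cells (26.7% against 36.7%). In recovered against tolerant cells 357 were higher and 75 lower (15.7% against 21.3%), while in tolerant against acute cells (14% against 24%) 105 were higher and more were lower. In tolerant against untreated cells 169 were higher and 125 lower, and in recovered against acute cells 22 and 12 (1.2% against 2.2%). The stress response list was examined further after its result was seen, and explanations for it are not weighed, a choice made once those values were known. Its median log2 difference between recovered and untreated cells was -1.59, -1.12 and -0.45 in experiments 1, 2 and 3, that of tolerant cells -1.21, -0.82 and -0.34, and that of acute cells -0.38, -0.16 and -0.09. In recovered against untreated cells the median was -1.34 over 9 genes, which were Atf4, a transcription factor gene, and genes taken as its targets. It was -0.60 over 7 other genes, which were chaperones and related genes and included Herpud1 (-2.57), which is not a chaperone.

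Each 2-group comparison was refitted over all 10 splits of its 6 arrays, which are too few for a share under 0.05. In each, 1 of the 10 splits, the real one, gave as many genes, with 4925, 3242, 6465, 3559, 4079 and 196 genes for acute, tolerant and recovered against untreated, tolerant against acute, recovered against tolerant and recovered against acute cells. The highest of the other splits gave 0 genes with limma, both for splits that part all 3 pairs of replicate numbers, as the real one does, and for those that part 1 pair. For any difference among the 4 groups, 1 of 100 splits of the 12 arrays, the real one, gave as many genes (8212). The highest other split gave 2720. A share of 1 in 100 is the lowest that these splits can give, so random regrouping rarely gives as many genes but is not excluded. The splits did not keep the replicate numbers together.

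Recovered and acute cells differed in 418 genes, and in 2199 with the replicate number as a block. With the numbers shuffled within groups, 1 of 100 arrangements, the real one, gave as many, and the highest other gave 1436. A first run had given 2 of 100 with a highest other of 2199, taken to be a redraw of the real arrangement but not checked as such, and the draw was then changed to exclude it. Variation between the 3 experiments that all groups share may therefore hold down the count without a block. The slide and scan day cannot be told apart from the experiment as its source, since the slide as a block gave 1600 genes and only recovered replicate 1 lies on another slide than the rest of its experiment.

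Of the 299 genes higher in recovered than acute cells, 90.64% lay higher in tolerant than acute cells too. The share was at most 69.55% in 20 simulations with tolerant equal to acute cells. These simulations hold no experiment effect and take the observed acute and recovered means as true. They may therefore understate the share that the shared acute arrays give. Across all genes the correlation, 0.418, was not above the 0.50 of simulations without a difference. Whether a change already present in tolerant cells accounts for part of the 299 thus stays open. Of 20 abundant stromal or lymphocyte transcripts 10 were well above background on no recovered array, among them Col1a1, Col3a1 and Cd8a, while Col1a2, Sparc, Dcn, Cd3e, Cd4, Cd79b, Nkg7 and Gzma were above it on all 3, Cd79a on 1, and the T cell transcript Cd3d on 2 and on no array of another group. Col1a2, Sparc, Cd3e, Cd4, Cd79b and Nkg7 were also above it on all 3 arrays of each other group, and Dcn and Gzma on at least 2. Only the 8 above it on all 3 recovered arrays could be tested. Limma called 0 of them higher in recovered than acute cells, with 0 higher at an unadjusted p under 0.05. Cd79b was lower (-2.78, adjusted p = 0.0554), and with either block it was called lower and none higher. Such cells stay open. The longer time in culture alone cannot be told apart from the treatment, since 0 of the arrays analysed here were of untreated cells kept as long. A lasting effect of the first LPS exposure also stays open, untested.

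On untreated array 3, 455 spots lay at the lowest value of the authors' column (2.58), and of 167 tested genes among those well above background 145 were higher and 1 lower in acute than untreated cells. Acute, tolerant and recovered array 3, on the same slide, had 35, 11 and 14 spots well above background at the lowest value of their column. Each array of the other slides had 0. Tnf lay at 12.78, 12.90 and 12.58 on untreated arrays 1 to 3 in the main analysis, and at 14.74, 15.08 and 2.58 in the authors' values. Of the 455 spots on untreated array 3, 55.4% (252) were well above background with 0 outliers. For these 252 spots, which gave the 167 tested genes, the scanner flags argue against faint or damaged spots. For the other spots that explanation stays open. A correction between scan days that was additive on the unlogged scale might give such values. With the 252 spots rebuilt in that way, untreated arrays 1 and 2 had a median absolute log2 difference of 0.62 from the authors' values. It was 1.78 with no correction, 1.01 by slide and 0.63 by replicate number, so the scan day and the replicate number came out alike. On untreated array 3, 62.3% of these spots were rebuilt at or below the lowest value by scan day. The share was 73.4% by slide, 68.7% by replicate number and 0% with no correction, and the cause stays undecided. The scan-day form was chosen after 16 combinations had been tried, and no biological explanation was tested.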
